A study of Mus musculus with 8 samples.

How the data were processed

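RNA sequencing of mouse heart ventricles at embryonic day 14.5 was re-analysed from the processed table of 1 series. The labels give 8 libraries of polyadenylated RNA read from 1 end, 4 from mutants in which a floxed Mib1 allele was deleted by Cre recombinase under the cardiac troponin T promoter and 4 from wild-type hearts. According to the series description, ventricles of 16 hearts per genotype were pooled into 4 replicates, so each library stands for a pool and not for an embryo.

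According to the submitters' notes, reads were trimmed with cutadapt 1.2.1 and quantified with RSEM 1.16 and Bowtie2 0.12.7 (version as named), and limma and edgeR were used; the genome build named is mm9. The deposited table holds 13869 genes by Ensembl identifier in 8 columns, and its name calls the values normalized counts. Tested on the values themselves, the deposited unit was a score and not a count. Each deposited value equalled a log2 CPM (count per 1000000) with a prior of 0.5 counts, relative to a normalized library size, multiplied by a constant per library that made the column sum to 1000000. The constants lay between 15.9683 and 16.0735. Dividing by them gave log2 CPM, and the counts behind 100% of the values then came back as whole numbers within a tolerance of 0.001 counts (largest distance 2.5e-05). The recovered totals ran from 6307634 to 11506082 counts per library, and the normalization factors of the authors from 0.9857 to 1.0129. How the authors chose the genes in the table is not given in the sources used here.

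Every value reported here was computed from log2 CPM, with the deposited normalization between libraries kept. Gene symbols were taken from the mouse GENCODE M21 annotation of assembly GRCm38 by Ensembl identifier, which matched 13428 of the 13869 genes and left 441 with no symbol. Because the named build was mm9, no genome position is given; gene order around Mib1 was read from GRCm38 as neighbours only. Transcript length and GC content came from the GENCODE M21 transcripts.

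The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level) with group as the only term. Genes with a mean log2 CPM of at least 0 were tested, 13740 of 13869. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Differences are log2 of mutant over wild type, with the moderated standard error (SE). Levels are means of CPM with the SD over 4 libraries. Mib1 was also compared by an exact permutation test over the 35 distinct splits of the 8 libraries into 4 and 4. Replicate numbers occur in both groups, but after removal of the group means libraries sharing a number correlated across genes at −0.04 to 0.1, and 0 mutant and 1 wild-type library resembled the library of its own number best, so the numbers were not used as pairs.

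The design, the gene lists, the named-gene rule and 28 alternative settings were chosen before the data were examined. The rule named Mib1, the 12 largest rises and the 12 largest falls among called genes with no overlap between the groups, a mean of at least 5 CPM in the higher group and a symbol that is no clone or predicted-gene name (Y-linked genes and Xist excluded), and from each list up to 4 called members of smallest p, or the member of smallest p where none was called. The rise part was met by 124 genes and the fall part by 152, and 76 distinct genes were named. Any other gene named, among them list members that were not called, was chosen after its values were seen. For each of 33 lists the members called over all genes and adjusted over the list alone were counted. Lists were compared with the other genes by limma's camera at a preset correlation of 0.01, adjusted over the 33 lists, with camera's estimated correlation and with fry beside it. All lists were written from general knowledge of heart cell types and pathways, and some genes stand in more than 1 list.

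Alternatives covered the pseudocount (0.1, 1 and 5 CPM), the filter on low values (none, or a mean of at least 5 CPM), quantile, median-ratio, total-count and upper-quartile scaling, eBayes with no trend or robust, array weights, voom precision weights, the replicate number as a block, the Y-linked, erythroid and macrophage levels and the total count as covariates, removal of erythroid genes, the threshold (0.01, 0.1, or 1.5-fold) and each library left out. Of the 34 alternatives, 6 were chosen after seeing the data: the pseudocount of 1 CPM, voom weights, the deposited scaling left in place, the macrophage and total-count covariates, and the libraries with the highest and lowest Xist level left out. DESeq2 and edgeR were not used, since the deposited table holds no counts; voom was run on the recovered counts instead. Outlying libraries among the 4 of a group were looked for by the ratio of Dixon (critical value 0.829).

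The pipeline was tested on simulated data with the size and depth of these libraries and 200 changed genes among 13740. Genes of similar level were given a common, median spread, and no library was made more variable than another. The shares recovered may therefore be better than in the real data. It called 58% of 50 genes changed 1.25-fold, 82% of 50 changed 1.5-fold, 94% of 50 changed 2-fold and 100% of 50 changed 4-fold. Of 179 simulated calls 12 were false (6.7%), and 0 had the wrong sign. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).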

Results

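Gene expression was measured in the heart ventricles of mouse embryos at E14.5 by sequencing of polyadenylated RNA. The comparison asked which transcripts differ when Mib1, which encodes an E3 ubiquitin ligase that Notch ligands require for signalling, is deleted in cardiomyocytes by Cre recombinase under the cardiac troponin T promoter. The mutant group held 4 libraries, with recovered totals of 11506082, 7828999, 6597943 and 7990530 counts, and the wild-type group 4, with 6973999, 8964058, 6307634 and 8289154. A floor of 3 counts corresponded to 0.265 to 0.472 CPM (counts per 1000000 of the normalized library size), for counting error only. Each library is a pool of embryos, and nothing in the sources used here says that the pools came from separate litters, so the p values measure the spread between these pools.

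Genes of the trabecular myocardium were lower in Mib1 mutant ventricles. Bmp10 (ENSMUSG00000030046), a trabecular growth factor, fell from 41.4 ± 2.32 to 8.5 ± 0.56 CPM (SD, n = 4), which was 4.87-fold. Nppa (ENSMUSG00000041616), the gene of atrial natriuretic peptide, fell 3.02-fold from 1090 ± 36.1 to 362 ± 35.9 CPM, and Gja5 (ENSMUSG00000057123), which encodes connexin 40 of the trabeculae and conduction system, fell 2.72-fold from 169 ± 3.67 to 62.3 ± 5.74 CPM. Tbx20 (ENSMUSG00000031965), Hey2 (ENSMUSG00000019789) and Fzd2 (ENSMUSG00000050288), from the list of compact myocardium, were higher, at 1.33-fold, 1.19-fold and 1.37-fold, Ntn1 of the same list was lower (−0.39 on the log2 scale), and the list as a whole was not called (median 0.06, camera adjusted p = 0.163). Markers of endothelial cells, macrophages, red blood cells and atrial myocardium were lower in the same mutant libraries, with list medians of −0.14, −0.41, −0.39 and −0.18 on the log2 scale. At an estimated correlation these lists had adjusted p values of 0.0764, 0.201, 0.146 and 0.356. In total 308 of 13740 genes tested by limma were called at an adjusted p under 0.05 (2.24%), 136 higher and 172 lower.

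Mib1 (ENSMUSG00000024294) itself stood at 100 ± 5.32 CPM in the mutants and at 161 ± 7.48 CPM in wild type (SD, n = 4), a fall of 1.6-fold. The 4 mutant libraries gave 106, 103, 95.4 and 96.4 CPM and the 4 wild-type libraries 150, 166, 161 and 167 CPM. The log2 difference was −0.68 ± 0.06 (SE; limma adjusted p = 8.62e-06), and the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give. The ventricles also hold cell types other than cardiomyocytes, and the counts cover the whole transcript, not the floxed part alone. Of the 20 tested genes nearest to Mib1, 9 had an unadjusted p under 0.05 and 0 were called.

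**Figure D1:**
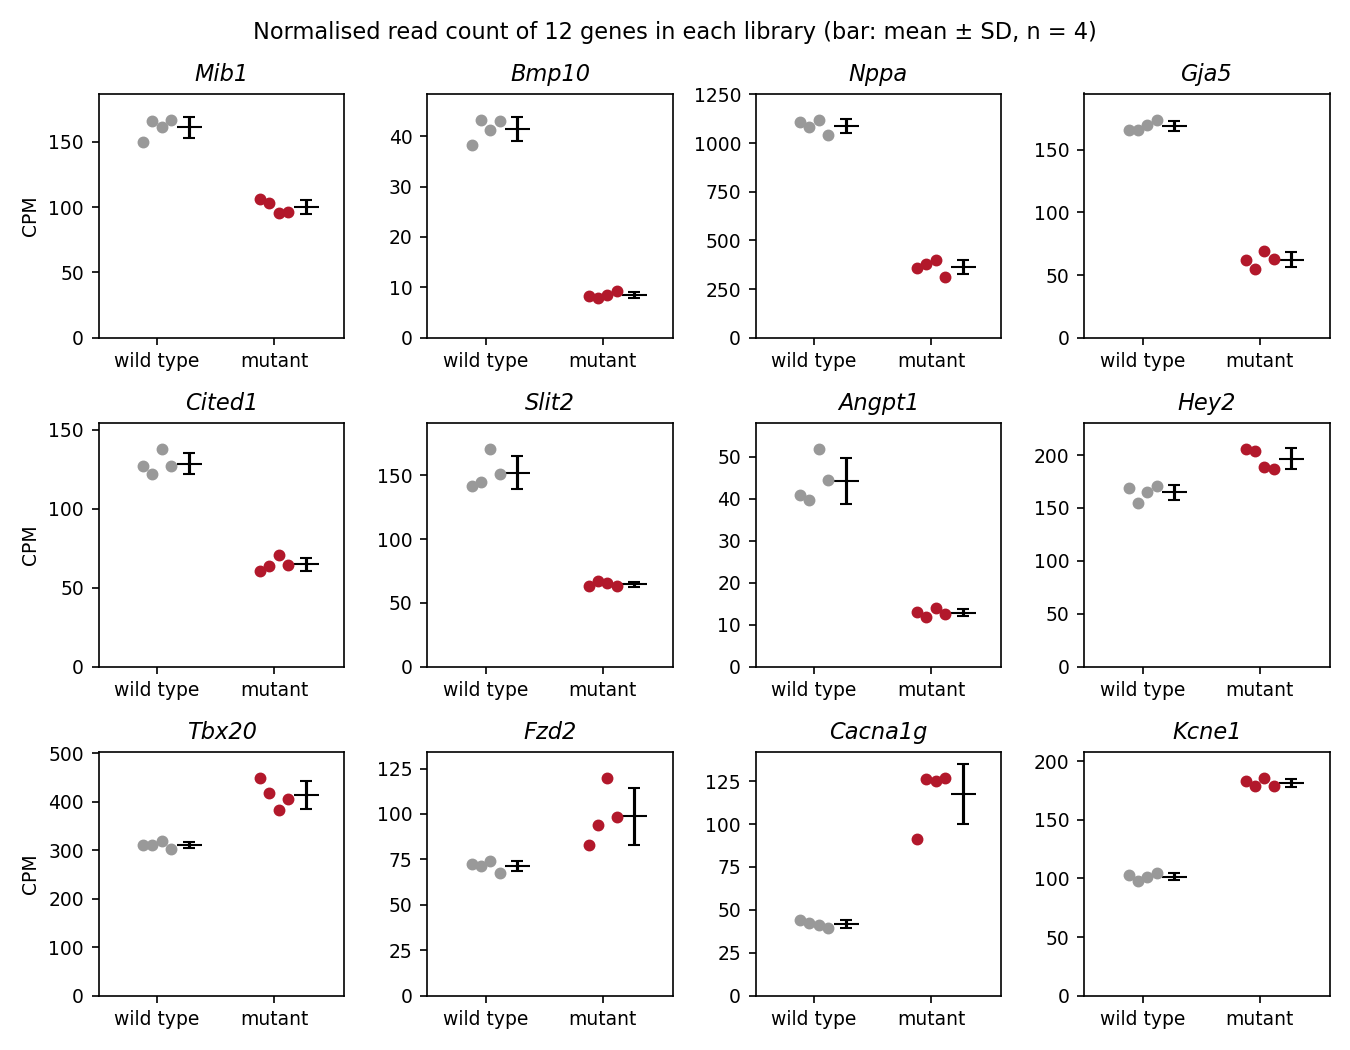
Normalised read count (CPM, linear axis from 0) of 12 genes in each of the 4 wild-type and 4 mutant libraries, with the mean and SD as bars. The groups do not overlap for any of the 12 genes, which the naming rule required of the largest rises and falls among them. Bmp10 lies near 8.5 CPM in the mutants against 41.4 CPM in wild type.

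The trabecular list had 14 tested members, of which 6 fell and 8 were not called. Besides Bmp10, Nppa and Gja5, the transcriptional coregulator gene Cited1 fell from 129 ± 6.94 to 64.8 ± 4.29 CPM, the guidance factor gene Sema3a fell by 0.85 on the log2 scale, and Cdkn1c, a CDK inhibitor, by 0.32 (call lost in 5 of the 8 fits with a library left out). Adjusted over the list alone, 8 fell, with Nppb at −0.41 and Cpne5 at −0.37 added. Irx3 stood at 0.16 and Irx5 at −0.1. The list median was −0.34, and camera gave an adjusted p of 4.95e-13, with an adjusted p of 0.00593 at an estimated correlation. This was the only list of the 33 that was called both ways. The atrial list was lower in the same libraries, with a median of −0.18 and 8 of 11 members below 0 (camera adjusted p = 0.0137, and an adjusted p of 0.356 with an estimated correlation).

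The compact list had 9 tested members, of which 3 rose and 1 fell. Tbx20, a T-box transcription factor, rose from 311 ± 6.95 to 414 ± 27.9 CPM, the Notch target and compact-layer repressor gene Hey2 from 165 ± 7.21 to 196 ± 9.77 CPM, and the Wnt receptor gene Fzd2 from 71.3 ± 2.78 to 98.8 ± 15.6 CPM. Ntn1, which encodes netrin 1, fell from 245 ± 16.4 to 187 ± 7.56 CPM. Tbx20 and Ntn1 kept their calls whichever library was left out, whereas Hey2 lost its call in 4 and Fzd2 in 2 of the 8 such fits. Adjusted over the list alone, 4 rose and 2 fell, Prdm16 standing at 0.29 and Ccnd2 at −0.16. The median was 0.06 with a camera adjusted p of 0.163, while fry, which tests whether the members move one way on balance, gave an adjusted p of 0.0194.

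Of 23 tested genes of trabeculation signals and cardiac jelly, 6 fell and none rose. Angpt1, the ligand of the endothelial receptor Tek, fell 3.42-fold from 44.2 ± 5.53 to 12.9 ± 0.926 CPM, and Tek itself fell by 0.25 on the log2 scale. Bmp5 fell by 0.79, Bmp7 by 0.21 and the versican-cleaving protease gene Adamts1 by 0.23. Wild-type replicate 3 was flagged for Bmp5 by the ratio of Dixon, at 20.1 CPM against 20.5, a gap within counting error at 127 counts. Adamts1 lost its call in 6 and Tek in 7 of the 8 fits with a library left out. Adjusted over the list alone, 8 fell and 1 rose, Erbb4 standing at 0.32, Bmp2 at −0.46 and Ephb4 at −0.19. The neuregulin gene Nrg1 stood at 0.27 ± 0.24 (SE). The median was −0.08 (camera adjusted p = 0.000119), with an adjusted p of 0.0764 at an estimated correlation. The pan-endothelial markers, Tek among them, were lower in these libraries too (median −0.14), with an adjusted p of 0.0764 at an estimated correlation.

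In the Notch pathway, 1 of 9 receptors and ligands was called. Dll1, a Notch ligand, fell from 11.1 ± 0.699 to 5.7 ± 0.799 CPM. Wild-type replicate 1, at 10 CPM from 69 counts, was flagged against the others at 11.3 to 11.5, a gap near the size of counting error. Adjusted over the list alone 5 fell, with Jag1 at −0.36, Dlk1 at −0.35, Jag2 at −0.38 and Notch4 at −0.26. The list median was −0.26 (camera adjusted p = 0.000125), and the adjusted p was 0.353 with an estimated correlation. The pan-endothelial, endocardial and coronary endothelial lists were lower in the same libraries, with medians of −0.14, −0.17 and −0.23, and none was called at an estimated correlation. Among 24 genes of pathway machinery 2 fell, over all genes and over the list alone, Mib1 and Ncstn (−0.28), a subunit of gamma-secretase; the median was 0 (adjusted p = 0.448) and Mib2 stood at −0.01 ± 0.11 (SE). Among 11 Notch target genes 2 rose and 1 fell. Hey2 and Unc5b (0.36) rose, Hey1 fell by 0.4, and adjusted over the list alone Gucy1a1 at −0.28 joined the falls; Unc5b in wild-type replicate 4 stood at 169 CPM against 192 to 194. All 3 calls were lost in some of the 8 fits with a library left out, Hey2 in 4, Unc5b in 5 and Hey1 in 6. The median of the targets was −0.06 (adjusted p = 0.98), and Hes1 stood at 0.19 and Nrarp at −0.11.

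Genes of calcium handling and ion channels went both ways. Of 24 tested, 2 rose and 4 fell, or 3 and 5 adjusted over the list alone, which added Cacnb2 at 0.24 and Kcnd2 at −0.54. Cacna1g, a T-type calcium channel gene, rose 2.79-fold from 41.7 ± 2.08 to 117 ± 17.3 CPM, with mutant replicate 1 at 91.4 CPM apart from 125 to 127 CPM in the others, and the connexin 45 gene Gjc1 rose by 0.3. Kcnd3, a transient outward potassium channel gene, fell 2.75-fold from 6.56 ± 0.825 CPM, Hcn4, a pacemaker channel gene, fell by 0.49 and the calcium-binding protein gene Hrc by 0.41. The median was 0.05 while the mean was −0.07 and camera pointed down (adjusted p = 0.798). Among 21 cardiac transcription factors Tbx20 and Tbx3 (0.5) rose, over all genes and over the list alone, and none fell. Hcn4 and Tbx3 each lost the call in 7 of the 8 fits with a library left out. The median of this list was −0.02, the mean 0.05 and the camera direction up (adjusted p = 0.174), and Gata4 stood at 0.13, Nkx2-5 at −0.08 and Tbx5 at −0.1.

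Sarcomere genes held no call among 24. Myom2 had the smallest p, at 0.68 ± 0.18 (SE; adjusted p = 0.0639), and adjusted over the list alone it was higher and Tnnt2, Des and Myl2, at −0.21, −0.21 and −0.17, were lower (1 and 3 genes). The median was −0.04 (camera adjusted p = 0.163). Of 13 fetal and wall stress genes 2 fell, Nppa and Xirp2 (−1.42; call lost in 4 of the 8 fits with a library left out), and adjusted over the list alone 3 fell and 1 rose, with Nppb at −0.41 and Ankrd1 at 0.34; the median was −0.06 (camera adjusted p = 0.0713, fry adjusted p = 0.0194). Of 20 disease genes of noncompaction and cardiomyopathy, Tbx20 rose and Mib1 and Hcn4 fell. Adjusted over the list alone 3 rose and 3 fell, Lmna standing at 0.32. The list median was −0.01 (0.01 when the deposited scaling was not undone) with the camera direction up (adjusted p = 0.926).

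The other largest rises were Kif1a, a kinesin gene, from 28.6 ± 3 to 67.6 ± 2.71 CPM (2.37-fold), and Kcne1, a potassium channel subunit gene, from 102 ± 3.39 to 182 ± 3.13 CPM (1.79-fold). The secreted Wnt inhibitor gene Wif1 rose 2.38-fold, the extracellular matrix gene Adamtsl2 2.23-fold, the arginine synthesis gene Ass1 2.26-fold and Smad9, a mediator of BMP signalling, 2.05-fold. Myrip rose 2.53-fold, Lancl3 1.98-fold, Cdh20 1.92-fold, Plekhh1 1.88-fold and Scd4 1.78-fold, and of these Myrip and Lancl3 each lost the call in 5 of the 8 fits with a library left out. Among the largest falls, Slit2, a guidance ligand gene, fell 2.35-fold from 152 ± 13 to 64.6 ± 1.99 CPM. Mal fell 3.67-fold, Gtsf1 3.06-fold and Tmem163 2.58-fold, all with wild-type means below 7 CPM. Gpnmb, which macrophages express, fell 3.18-fold and lost the call in 3 of the 8 fits; the macrophage list had a median of −0.41 in the same libraries. Among all calls, 41 higher and 77 lower genes differed at least 1.5-fold, and 12 higher and 29 lower genes at least 2-fold.

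**Figure D2:**
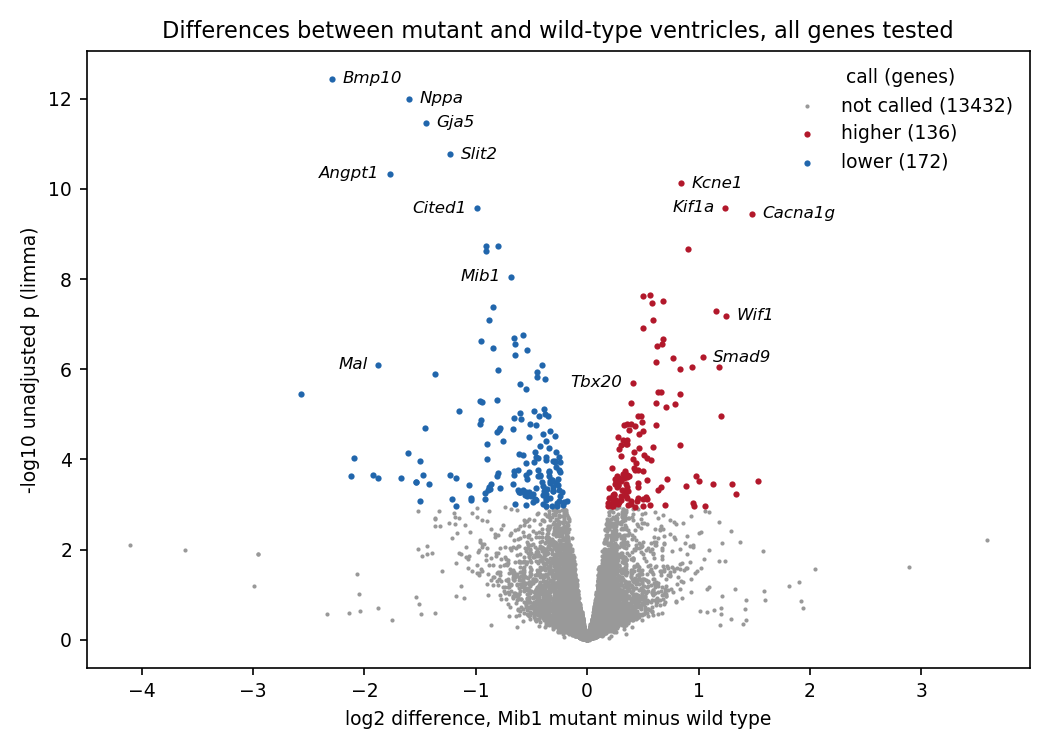
Log2 difference of mutant minus wild type against −log10 of the unadjusted limma p for all 13740 genes tested, with 136 genes called higher in red, 172 called lower in blue and the rest in grey. Bmp10, Nppa and Gja5 lie at the upper left, with log2 differences of −2.29, −1.6 and −1.45.

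Endocardial and endothelial markers were lower. Of 13 endocardial genes 4 fell and none rose: Plvap by 0.65, Vwf by 0.8, Npr3 by 0.46 and Adgrg6 by 0.33 on the log2 scale (5 fell adjusted over the list alone, with Cdh11 at −0.17). Adgrg6 lost its call in 4 of the 8 fits with a library left out, and Nfatc1 stood at 0.05. The median was −0.17 (camera adjusted p = 0.000194), with an adjusted p of 0.146 at an estimated correlation. Of 20 pan-endothelial genes 3 fell, Ramp2 by 0.37, Egfl7 by 0.37 and Tek by 0.25, and 8 fell adjusted over the list alone; Egfl7 lost its call in 6 and Tek in 7 of the 8 fits with a library left out. Pecam1 stood at −0.11 and Emcn at −0.02. The median was −0.14 (adjusted p = 6.67e-07), and the adjusted p was 0.0764 with an estimated correlation. Of 12 coronary endothelial genes the apelin receptor gene Aplnr fell by 0.65 and the fatty acid transporter gene Cd36 by 0.39, and Unc5b rose (4 fell and 1 rose adjusted over the list alone), and Cd36 and Unc5b each lost the call in 5 of the 8 fits with a library left out. Their median was −0.23 (adjusted p = 0.0262), with an adjusted p of 0.146 at an estimated correlation.

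Macrophage and erythroid markers were lower as well. Of 18 macrophage and leukocyte genes 3 fell: Lyz2 from 30.6 ± 2.64 to 16.6 ± 0.854 CPM, Tyrobp from 5.24 ± 0.313 to 2.36 ± 0.0484 CPM and C1qc from 8.37 ± 1.2 to 4.67 ± 1.19 CPM. Adjusted over the list alone 7 fell and 1 rose, with Csf1r at −0.33 and Lyve1 at 0.34. Of the 18 members 16 lay below 0, but by uneven amounts: Adgre1 stood at −0.21, Mrc1 at −0.08 and F13a1 at 0.08. The median was −0.41 (adjusted p = 3.67e-07), and the adjusted p was 0.201 with an estimated correlation. Of 15 erythroid genes 2 fell, the membrane skeleton gene Ank1 by 0.55 and the alpha globin gene Hba-a1 by 0.55, from 789 ± 77.2 to 550 ± 133 CPM (7 fell adjusted over the list alone). Hba-a1 and C1qc each lost the call in 6 of the 8 fits with a library left out. The erythroid median was −0.39 (adjusted p = 8.03e-05), with an adjusted p of 0.146 at an estimated correlation.

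Markers of other cell types were also compared. Of 11 atrial genes Kcnj3, a potassium channel gene, fell by 0.67 and the atrial light chain gene Myl7 rose by 0.37, and adjusted over the list alone 4 fell and 1 rose, with Mybphl at −0.93 and Nr2f2 at −0.31; Myl7 lost its call in 6 of the 8 fits with a library left out. The atrial median was −0.18 (adjusted p = 0.0137), and the adjusted p was 0.356 with an estimated correlation. None of 13 epicardial genes was called; Krt8 stood at 0.74 ± 0.2 (SE) and Wt1 at 0.09, 3 were higher adjusted over the list alone, and the median was 0.02 (adjusted p = 0.384). Of 20 fibroblast and cushion genes Fbln1 fell by 0.34, over all genes and over the list alone, and the median was −0.04 with a mean of 0.02 and a camera direction down (adjusted p = 0.738). Of 12 smooth muscle and pericyte genes Acta2 rose from 846 ± 71.2 to 1090 ± 50.7 CPM and Cnn1 by 0.3, and Abcc9 fell by 0.34, the calls of Cnn1 and Abcc9 each being lost in 5 of the 8 fits with a library left out; the median was 0.02 (adjusted p = 0.473), and 3 rose and 2 fell adjusted over the list alone. None of 7 neural genes was called over all genes or over the list alone; Fabp7 stood at −0.67 and the median at 0.28 (adjusted p = 0.926). The only tested gene of the liver, lung, thymus and skeletal muscle list, Ahsg, stood at −0.55 ± 0.37 (SE) and 1.76 CPM in wild type (list adjusted p = 0.455).

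Genes of oxidative metabolism were lower by small amounts. Of 26 fatty acid oxidation genes 4 fell and none rose: Acsl1 by 0.37, Acaa2 by 0.24, Cd36 by 0.39 and Hadha by 0.18 (8 fell adjusted over the list alone). With a library left out, Acsl1 lost its call in 2, Acaa2 in 3, Cd36 in 5 and Hadha in 6 of the 8 fits. The median was −0.12 (adjusted p = 4.53e-06), with an adjusted p of 0.146 at an estimated correlation. Of 28 oxidative phosphorylation genes 27 lay below 0, and 2 fell: Cox6a2 by 0.51 and Cox8b by 0.61, both muscle isoforms of cytochrome oxidase subunits (3 fell adjusted over the list alone, with Ndufb8 at −0.16); Cox8b lost its call in 5 of the 8 fits with a library left out. The median was −0.09 (adjusted p = 3.67e-07), and the adjusted p was 0.146 with an estimated correlation; a trend with transcript length, GC content and level accounted for part of it, leaving −0.05. The 13 mitochondrially encoded genes had a median of 0 (adjusted p = 0.94) and no call over all genes or over the list alone, with mt-Nd3 at −0.12. Of 21 glycolysis genes Aldoc rose from 19.8 ± 1.87 to 32.4 ± 3.79 CPM, the median was −0.06 (adjusted p = 0.236), and 2 rose and 3 fell adjusted over the list alone, with Gapdh at −0.77 ± 0.22 (SE) and Ldhb at −0.16.

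Cell cycle genes did not pass the test. The 20 S phase genes had a median of −0.03 (adjusted p = 0.405) and E2f1 at −0.16 ± 0.06 (SE), and the 24 genes of G2 and M phase a median of 0.04 (adjusted p = 0.122) and Ect2 at 0.19 ± 0.06 (SE), with no call over all genes or over either list alone. Of 4 CDK inhibitors Cdkn1c fell from 268 ± 17.1 to 215 ± 19.7 CPM, over all genes and over the list alone; their median was 0.07, the mean −0.01 and the camera direction up (adjusted p = 0.942). The 19 hypoxia genes had a median of −0.01 (adjusted p = 0.926), Ankrd37 standing at −0.41, and the 16 immediate early genes that respond to dissection a median of −0.03 (adjusted p = 0.796), Egr1 standing at 0.28, again with no call over all genes or over either list alone.

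**Figure D3:**
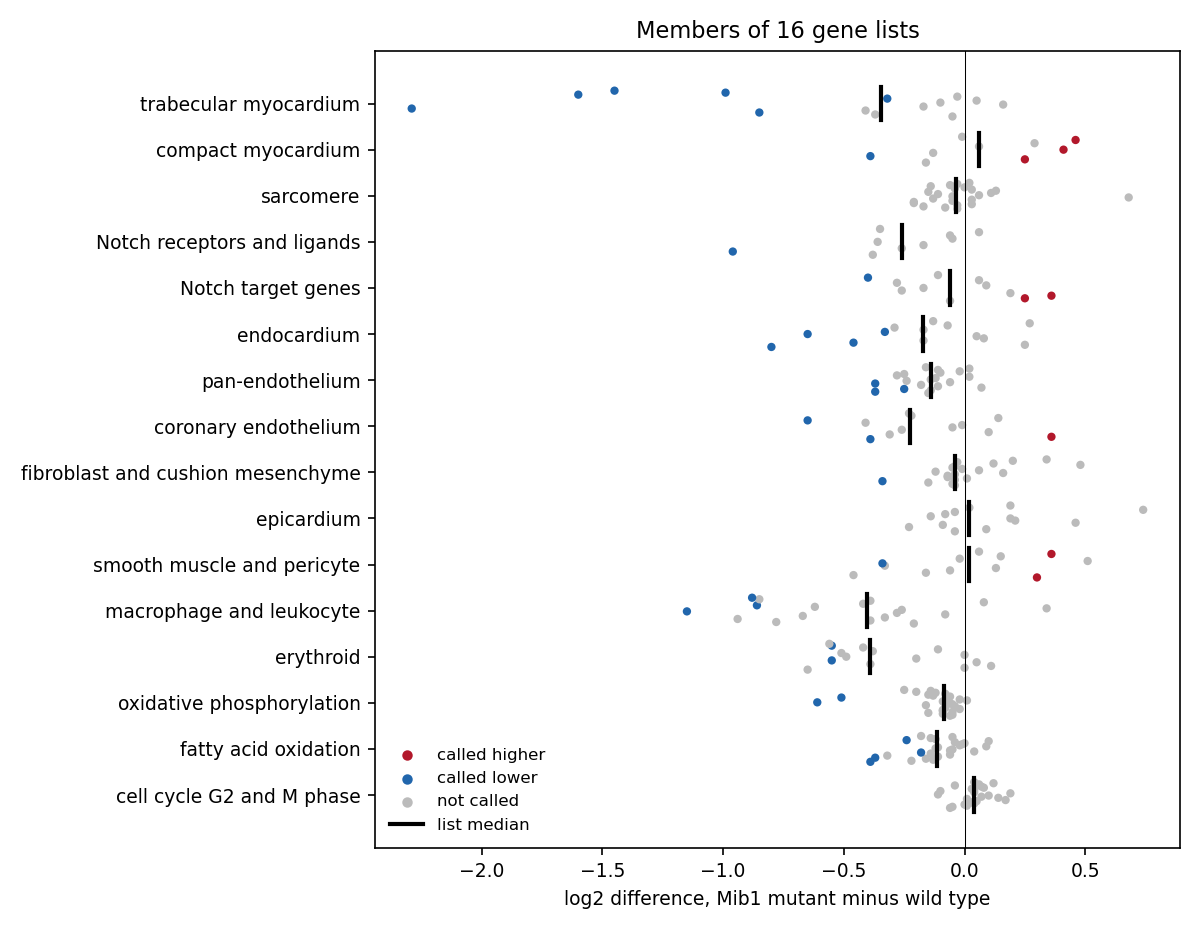
Log2 difference of each tested member (points, with genes called higher in red, called lower in blue and the rest in grey) and the median (bar) for 16 of the 33 gene lists. The trabecular list has a median of −0.34 and the compact list one of 0.06.

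The pools differed in Xist and Y-linked transcripts, which mark female and male embryos. Xist stood at 1130, 278, 559 and 791 CPM in the mutants and at 366, 586, 288 and 11.6 CPM in wild type, a log2 difference of 1.9 ± 0.9 (SE), not called (list adjusted p = 0.287); without wild-type replicate 4 the difference was 0.63. Ddx3y stood at 32.1, 73.9, 35.1 and 29.3 CPM in the mutants and at 55.4, 45.6, 62.8 and 81.9 CPM in wild type. The 4 Y-linked genes had a median of −0.48 and no member called over all genes or over the list alone (list adjusted p = 0.0215, and an adjusted p of 0.441 with an estimated correlation). With the libraries of highest and lowest Xist left out, a setting chosen after seeing the data, 224 genes were called.

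Of the 308 called genes, 305 showed no overlap between the groups, as did 1226 of all genes tested (8.92%, against 2.86% by chance), and 2033 genes had an unadjusted p under 0.05, against 687 expected by chance. By camera at the preset correlation 12 of the 33 lists were called, all lower, and at an estimated correlation 1 was, the trabecular list. By fry 9 of these 12 were called, without the Notch receptor and ligand, atrial and Y-linked lists, and 2 others, compact myocardium (median 0.06) and fetal and wall stress genes (median −0.06). The count of 308 moved to 183 and 477 without mutant replicates 2 and 3, to 146, 147 and 161 without wild-type replicates 1, 2 and 3, to 179 with no trend in eBayes and to 490 with array weights, and 25 of 64 other named genes with a call lost it when 1 of the 8 libraries was left out. It fell to 155, 71 and 26 with the Y-linked, the erythroid and the macrophage level as a covariate. All 308 genes kept their direction in each of these fits, but they were picked by this difference in the same libraries. The Y-linked, erythroid and macrophage levels were themselves lower in the mutants (list medians −0.48, −0.39 and −0.41), so these covariates share variation with genotype. A call can then be lost through a larger SE with little change in the difference, and the counts do not tell which.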

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

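The tests of atrial tissue, pool sex, the share of other cell types, blood content and cardiomyocyte share were chosen after the result was seen; the tests of library splits and of transcript length, GC content and level were chosen before.

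Among 154 groups of 4 libraries (each of 76 named genes and the library total, in each genotype), 4 held a library far from the other 3 by the ratio of Dixon, against 7.7 expected by chance. Cacna1g stood at 91.4 CPM in mutant replicate 1 and at 125 to 127 CPM in the other mutants. Dll1 stood at 10 CPM in wild-type replicate 1 and at 11.3 to 11.5 CPM in the other wild types. Unc5b stood at 169 CPM in wild-type replicate 4 and at 192 to 194 CPM in the others. Bmp5 stood at 20.1 CPM in wild-type replicate 3 and at 20.5 CPM in the others. The Dll1 and Bmp5 gaps, at 69 and 127 counts, are of the size of counting error or smaller. The ratio covers named genes and totals only. Compared in pairs over all genes by chi-square per degree of freedom, mutant replicate 1 gave 4.99, 9.26 and 7.68 against mutant replicates 2, 3 and 4. The other mutant pairs gave 3.15 to 4.86 and the wild-type pairs 1.94 to 4.11. This measure rises with depth, and mutant replicate 1 had the highest total.

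The 308 genes called between the genotypes were tested against relabelled libraries. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many calls, and the highest of the others gave 2. A chance assignment of the libraries is thus unlikely, at 1 of 35, the smallest share this test can give. Every other split mixes the genotypes, so the genotype difference widens its spread and lowers its count. The gap from 308 to 2 is therefore no measure of strength. A difference between pools that runs along with genotype would give the same outcome.

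The lower trabecular genes were weighed against the dissection and the sex of the pools. With the Y-linked level as a covariate the trabecular list kept a median of −0.34 (camera adjusted p = 8e-12), which argues against pool sex as the cause. Less atrial tissue in the mutant pools stays open, since the atrial list median of −0.18 lay above the trabecular one by 0.16 with a bootstrap interval of −0.33 to 0.83; of its abundant members Myl7 rose (0.37, 298 to 387 CPM) and Myl4 stood at −0.11 (1110 to 1030 CPM), and the lowest member, Mybphl, stood at −0.93, but fetal ventricles express Myl7 and Myl4 too, so they do not settle it. A second version with only the 6 called trabecular genes (median −1.22, difference 1.04, interval 0.34 to 1.76) was run after the first and picks genes by their fall, so it decides nothing. Loss of Mib1 in cardiomyocytes, the difference the design names, is a hypothesis that may account for the fall and cannot be told apart from an atrial share, because the interval spans 0.

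The lower macrophage, endothelial and erythroid markers, whose lists lost their calls at an estimated correlation (adjusted p = 0.201, 0.0764 and 0.146), were weighed against tissue makeup. A lower share of every cell type other than cardiomyocytes would lower fibroblast, epicardial and smooth muscle markers as well. These lists had medians of −0.04, 0.02 and 0.02. Their joint median lay 0.22 above that of the macrophage, pan-endothelial and erythroid markers (bootstrap interval over genes 0.12 to 0.39). That interval treats genes as independent and leaves out the spread between pools, so it is too narrow where members of a list move together. Within that limit, the fall was not shared by all markers of other cell types. With the erythroid level as a covariate the macrophage list stood at −0.48 and the pan-endothelium list at −0.16, which argues against blood content as the cause of the fall in these 2 lists; for the erythroid list the covariate is made of its own genes, so lower blood content stays open there. Fewer of these cells and a lower transcript level within them may each give the pattern, and these libraries of whole ventricles hold no test between them.

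The lower oxidative phosphorylation genes, whose list lost its camera call at an estimated correlation (adjusted p = 0.146), were weighed against transcript properties and tissue makeup. A trend of the difference with transcript length, GC content and level, fitted over 13314 genes, explained 5.13% of the variance, and its removal moved the list median from −0.09 to −0.05 (interval −0.08 to −0.02). By this interval, which resamples genes and leaves out the spread between pools, the trend accounts for part of the fall and not for all of it. Fatty acid oxidation stood at −0.09 after removal. A lower share of cardiomyocytes stays open, since the sarcomere list lay above the oxidative phosphorylation list by 0.05 with an interval of 0 to 0.11. The unrounded lower bound was 0.0043, and the requirement that the rounded bound lie above 0 was set after it was seen.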

How the results depend on the processing

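The alternatives with a pseudocount of 1 CPM, voom weights, the deposited scaling left in place, a macrophage or total-count covariate, or the libraries of extreme Xist level left out were chosen after the result was seen.

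Against 308 called genes (136 higher, 172 lower), eBayes with no trend called 179 (70 and 109), array weights 490 (226 and 264), the Y-linked covariate 155 (68 and 87), the erythroid covariate 71 (34 and 37) and the macrophage covariate 26 (12 and 14); the cause was not tested. The Y-linked, erythroid and macrophage levels were lower in the mutants, so these covariates share variation with genotype and can enlarge the SE. Their lower counts therefore do not show that the lost calls came from sex, blood or macrophage content. By construction, a threshold of 0.01 called 119 (54 and 65), of 0.1 551 (252 and 299) and a 1.5-fold minimum 118 (41 and 77). Leaving out a library gave 146 to 477 genes (64 to 208 higher, 81 to 269 lower): 183 without mutant replicate 2, 477 without mutant replicate 3, and 146, 147 and 161 without wild-type replicates 1, 2 and 3. With the replicate number as a block, which the libraries do not bear out as a pairing, 240 were called, 223 of them among the 308. The other alternatives gave 224 to 374. Among the 308 genes, each kept its sign under every alternative that tested it. For the 305 with no overlap between the groups this was fixed in advance when a library was left out, and for all of them under a threshold or filter. Under the scalings the median of all genes lay at −0.007 to 0.013. Mib1 stood at −0.79 to −0.66 and stayed called (highest adjusted p 0.00502), and at −0.71 to −0.66 with a library left out.

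Of 75 other named genes 64 were called. None of these changed sign, which for groups with no overlap was fixed in advance when a library was left out. Under every alternative 12 kept their call: Adamtsl2, Angpt1, Ass1, Bmp10, Cacna1g, Cited1, Gja5, Kcne1, Kif1a, Nppa, Plekhh1 and Slit2. With a library left out 39 kept it in all 8 fits and 25 lost it in at least 1: Acsl1, Fzd2, Acaa2, Gpnmb, Adgrg6, Hey2, Xirp2, Abcc9, Cd36, Cdkn1c, Cnn1, Cox8b, Lancl3, Myrip, Unc5b, Adamts1, C1qc, Egfl7, Hadha, Hba-a1, Hey1, Myl7, Hcn4, Tbx3 and Tek. The calls lost were 8, 18, 4 and 10 without mutant replicates 1 to 4, and 25, 22, 20 and 18 without wild-type replicates 1 to 4. Over all alternatives, 1846 of 2162 values of named genes stayed on their side of the threshold, 307 fell short of it, 7 passed it and 2 changed sign, both of genes not called: Xist (−0.79 with the erythroid covariate) and Ddx3y (0.16 with the macrophage covariate).

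Of the 12 lists called, 1 (trabecular) stayed called with an estimated correlation, and 9 by fry, which called 2 others (11 in all). With a library left out 10 to 13 lists were called, with 9 to 12 of the 12 among them; the trabecular list alone kept its call under every alternative. Of 1021 list values 939 kept sign and side, 33 fell short, 12 passed and 37 changed the sign of their median. Counted by camera's direction, a definition tried before the median was chosen, 54 did. With the macrophage covariate the medians turned to 0.16 (Notch targets), 0.03 (sarcomere), 0.01 (cardiac transcription factors), 0.06 (fetal and wall stress), 0.06 (fibroblast), 0.11 (macrophage, by construction), −0.21 (neural), 0.11 (glycolysis), 0.07 (hypoxia), 0.07 (immediate early), 0.29 (Y-linked) and 0.06 (disease genes). With the erythroid covariate they turned to −0.03 (calcium handling and ion channels), 0.02 (cardiac transcription factors), 0.02 (erythroid, by construction) and −0.79 (Xist). Cardiac transcription factors stood at 0.02 with the Y-linked covariate, at 0.01 with the total count and at 0.01 with the Xist libraries out. With a library left out they ran from −0.04 to 0.02, hypoxia from −0.03 to 0.03, immediate early genes from −0.06 to 0.01, disease genes from −0.02 to 0.03, epicardium from −0.07 to 0.1 and smooth muscle from −0.01 to 0.07. The rest were neural at −0.21 and hypoxia at 0.02 with a mean of at least 5 CPM, epicardium at −0.04 with voom weights, and disease genes at 0.01 with the deposited scaling and with the Xist libraries out. Apart from those 2 made by construction the cause was not tested.

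The planned DESeq2 and edgeR fits were not run, since count models were kept for tables deposited as counts; voom on the recovered counts, in their place, called 316 genes. On simulated data at this depth, in which genes of similar level had a common spread, 82% of 1.5-fold changes were called.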

Other observations

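The tests of the guidance and imprinted families were chosen after the result was seen, and the test of the genes next to Mib1 before; the genes named in the next paragraph were chosen after their values were seen.

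Further genes outside the lists were called. Among those known from macrophages and lysosomes, the pore-forming protein gene Mpeg1 fell by 0.81 on the log2 scale, the lysosomal protease gene Ctss by 0.81 and the phagocytic receptor gene Trem2 by 1.18. Apoe fell from 168 ± 16.9 to 117 ± 20.3 CPM (SD, n = 4), and Ctsd and Grn fell by 0.24 and 0.26. Among those known from BMP and TGF-beta signalling, the BMP target Id2 rose by 0.67, Skil by 0.41, Pmepa1 by 0.44, Smad2 by 0.31 and the activin antagonist gene Fstl3 by 0.54. Of matrix genes, Thbs4 rose by 0.77, Col12a1 by 0.68 and Tnc by 0.39. Kcnk3, a background potassium channel, fell from 71 ± 2.76 to 37.8 ± 2.74 CPM. Gpx3, an extracellular glutathione peroxidase, fell from 359 ± 19.4 to 207 ± 14 CPM, and the endothelin receptor gene Ednrb from 148 ± 8.29 to 93.8 ± 9.12 CPM. Gria2, a glutamate receptor gene, fell by 2.57 and Sfrp5, a secreted Wnt antagonist, by 2.09, both at low level (3.36 and 3.1 CPM in wild type). Irx1 and Irx2, of the Iroquois family, fell by 0.92 and 0.46. No enrichment was tested for these groups.

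The genes of axon guidance families (semaphorins, plexins, neuropilins, Slit, Robo, netrin, Unc5, ephrin and Eph genes) held 9 called genes among 58 tested (15.52%), against 2.19% of other genes. Slit2 fell by 1.23, Sema3a by 0.85, Epha4 by 0.6, Plxnc1 by 0.58, Sema3g by 0.55, Sema3b by 0.47 and Ntn1 by 0.39 on the log2 scale, and Robo1, a receptor of Slit2, rose by 0.56 and Unc5b, a receptor of Ntn1, by 0.36. A two-sided Fisher exact test gave p = 5.16e-06 (1.55e-05 adjusted over the 3 families and neighbourhoods tested). Imprinted genes held 5 called genes among 46 tested (10.87%, against 2.21% of other genes), and all 5 were lower: Mest, Igf2r, Cdkn1c, Ddc and Klf14 at −0.54, −0.35, −0.32, −0.43 and −1.21. The exact p was 0.00354, and 0.00354 after adjustment. Both families were picked from the called genes out of an unknown number of families, so these p values overstate the evidence, and a lowered imprinted set and a shifted guidance set are hypotheses that may hold in other pools.

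DNA flanking the targeted Mib1 allele was tested as a source of differences around the gene. Of the 20 tested genes nearest to Mib1 in the gene order of GRCm38, 9 had an unadjusted p under 0.05, against 14.75% of other genes. The Fisher exact p was 0.00119 (adjusted 0.00178). Of these 9 genes 7 were higher and 2 lower, and 0 were called by limma; among them Abhd3 stood at 0.85, Esco1 at 0.29, Npc1 at 0.23 and Fzd8 at −0.62. The next 20 genes held 5 and the 28 beyond them 7, a share of 25% in each, and each of these windows held 1 called gene. Strain differences near the targeted allele may contribute to these values, but the p treats neighbouring genes as independent, and the strain of origin is not given in the sources used here.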
